A study of Mus musculus with 2 samples.

How the data were processed

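Single cells from mouse maxillary periodontium, the tissue that anchors the upper teeth, had been profiled in 2 droplet libraries, titled 377P and RP. Per the labels' protocols, the libraries were made with the 10x Genomics Chromium 3' v3 kit, in which each captured mRNA carries a unique molecular identifier (UMI). The series title speaks of the resolution of periodontitis in diabetes. The labels do not say what either title stands for, so the libraries are called by their titles and neither is treated as a control. Each title has 1 library, and nothing in the labels says how many animals each one pooled.

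The deposited matrices hold raw counts of UMIs per gene and barcode, and no normalisation had been applied to them. Per the file headers they were written by Cell Ranger 7.0.1, and per the submitters' processing notes Cell Ranger and STAR were used with the mm10 mouse genome. The annotation release and the handling of intronic reads are not given in the sources used here. Each matrix lists 32285 genes. The lowest barcode total was 500 UMIs in both libraries. The 377P matrix holds 15466 barcodes and 127094166 UMIs, with a median of 5288 UMIs per barcode. The RP matrix holds 18112 barcodes and 120909095 UMIs, with a median of 4144.

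Barcodes were kept with at least 200 genes and at most 20% mitochondrial UMIs. In 377P, 115 barcodes (0.744%) were above the mitochondrial limit, and in RP 819 (4.52%). A further 8 barcodes of RP had fewer than 200 genes. Doublets were called in each library with Scrublet, run through Scanpy 1.11.5 with an expected share of 12%, and were removed: 832 in 377P (5.42%) and 514 in RP (2.97%). This left 14519 cells in 377P and 16776 in RP. The kept cells had medians of 5102 and 4309 UMIs.

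Counts were scaled to 10000 UMIs per cell and log-transformed. The 3000 most variable genes gave 40 principal components, and a graph of 20 nearest neighbours was clustered with the Leiden algorithm (igraph 0.11.9) at resolution 1.0, both libraries together and without integration. Clusters were named only from marker genes listed before the data were examined. The scoring limits, which asked for at least 3 detected markers, and the merging of B with plasma cells and of T with NK cells were set after the clusters had been seen. The clusters that these limits left unnamed held 4.72% of the kept cells of 377P and 1.22% of those of RP.

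Shares of cells are given with exact 95% binomial (Clopper-Pearson) intervals. For expression, UMIs were summed over the cells of a class in a library and divided by the class total to give counts per 1000000 UMIs (CPM), with exact 95% Poisson intervals. Folds are ratios of CPM with the exact interval of a ratio of Poisson counts. All these intervals cover counting error only. With 1 library per title, a difference has no replicate check, and no p-value, standard error or number of changed genes is given. A count of 0 was set to a floor of 3 counts per library in log2 ratios. For a named gene with a count of 0, the lower end of the exact interval of its fold is given as a bound. Log2 ratios are RP over 377P throughout. Classes were compared if they held at least 200 kept cells in each library, which 8 did.

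A total of 30 gene lists and the classes they belong to were fixed before the data were examined, as were the filters, the rule for named genes and most alternative settings. A list's median log2 ratio was taken over members with at least 20 UMIs in the class, where at least 5 remained. It was set among 10000 random lists of the same size, each member drawn from the 100 genes nearest in mean expression. A list is said to stand apart below the percentile 2.5 or above 97.5, as a description of these libraries. Intervals of list medians came from 500 Poisson draws.

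The named genes had at least 50 UMIs and 50 CPM in the class in the library where they were higher. Their CPM there was at least 20% of their highest CPM over the named classes with at least 50 cells, a guard against free RNA. Mitochondrial, ribosomal protein, hemoglobin, immunoglobulin, T cell receptor, predicted and sex-linked check genes were left out. Genes were ranked by the bound of the fold's interval nearest to 1. The 4 classes with the most cells, by the smaller count of the 2 libraries, name 4 genes in each direction and the others 2, which made 48 entries of 29 genes. The 2 highest members of a list in each direction could be named as well.

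The guard did not count unnamed clusters, and 4 odorant-binding protein genes that lead an unnamed cluster of 377P filled 22 of the 48 entries. An added guard, chosen after these values were seen, also counts the unnamed clusters, and the genes that took the freed places are described as such. An earlier form of it that counted every cluster took out 29 of the 48 entries and was set aside. Coordinates are from the GENCODE annotation of GRCm38 (mm10), matched by Ensembl identifier.

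The steps for folds and lists were tested on simulated counts drawn from the real class totals. For fibroblasts, over 14593 genes, 95.6% of the intervals held the true fold, and 4.50% of the unshifted lists stood apart. For the monocyte or macrophage class, over 10076 genes, these shares were 95.7% and 3.50%. Both simulated libraries were drawn from 1 profile, apart from 200 genes with set folds, and the lists were random genes. The shares therefore check the arithmetic of the steps only. They give no rate for lists of genes that vary together or for libraries with different mixes of cells.

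Alternatives changed 1 choice at a time: stricter limits on genes and mitochondrial UMIs, no doublet removal, Leiden resolutions of 0.5 and 2.0, separate clustering of each library, other denominators for shares, scaling to the median ratio, equal weight per cell, thinning to 1000 UMIs, and other rules for list members. One rule for list members left out those whose CPM in the class was under 20% of their highest over the named classes in both libraries. These are called members that free RNA could supply. The rule also takes out genes that the class itself expresses at a lower level, so it does not show that free RNA supplied them. Thinning left out 841 kept cells of 377P and 1980 of RP. A limit of 1000 UMIs per cell, single clusters or pairs of clusters in place of whole classes, and classes with at least 100 cells were added after the data had been seen. Scaling to the median ratio and the limit of 100 cells leave the percentiles of lists in the compared classes as they were. Both are still counted among the settings given for lists. The scripting used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.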

Results

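The data set holds 14519 kept cells of library 377P and 16776 of library RP, both from mouse maxillary periodontium. Cells of 14 named classes were found. Epithelial cells, fibroblasts and immune cells made up most of 377P, and RP held in addition a large class of gland or respiratory epithelial cells. Both libraries held cells of male animals: the Y-linked gene Ddx3y had 13562 UMIs in 377P and 11774 in RP, and Xist, which is transcribed from the inactive X chromosome of female cells, had 10 and 5. With 1 library per title, every value below compares these libraries and not the conditions behind their titles.

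Lymphocytes made up a larger share of 377P, and gland, vascular and myeloid cells a larger share of RP. B or plasma cells were 21.3% of the kept cells of 377P (95% interval 20.6 to 22.0) and 3.36% of those of RP (3.09 to 3.64). T or NK cells were 13.2% (12.6 to 13.7) and 4.25% (3.95 to 4.57). All immune classes together came to 39.2% of 377P and 14.7% of RP. The gland or respiratory epithelial class was 1.96% of 377P (1.74 to 2.19) and 16.6% of RP (16.1 to 17.2). Within it, cluster 18, with a median of only 696.5 UMIs in RP, made up 0.70% of 377P and 8.09% of RP. Blood endothelial cells were 3.66% (3.36 to 3.98) and 10.1% (9.63 to 10.5), perivascular cells 4.18% (3.86 to 4.52) and 7.70% (7.30 to 8.11), and monocytes or macrophages 3.75% (3.44 to 4.07) and 5.88% (5.53 to 6.24).

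Epithelial cells were 25.6% of 377P (24.9 to 26.4) and 22.3% of RP (21.6 to 22.9), and fibroblasts 17.8% (17.2 to 18.5) and 23.1% (22.5 to 23.7). Lymphatic endothelial cells, Schwann cells, neutrophils, mast cells or basophils, neuronal cells and chondrocytes were each under 2% of either library. No cluster took the name of osteoblast lineage, osteoclast or dendritic cells at this resolution. The T or NK share depended on how clusters were named: among cells with at least 1000 UMIs its log2 ratio of shares was 0.22 against -1.63. Of the 1912 T or NK cells of 377P, 1346 then fell in clusters that took no name and 24 were left out for depth. Within non-immune cells the fibroblast ratio was -0.11 against 0.37, and with each library clustered on its own the gland ratio was 0.99 against 3.09.

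**Figure D1:**
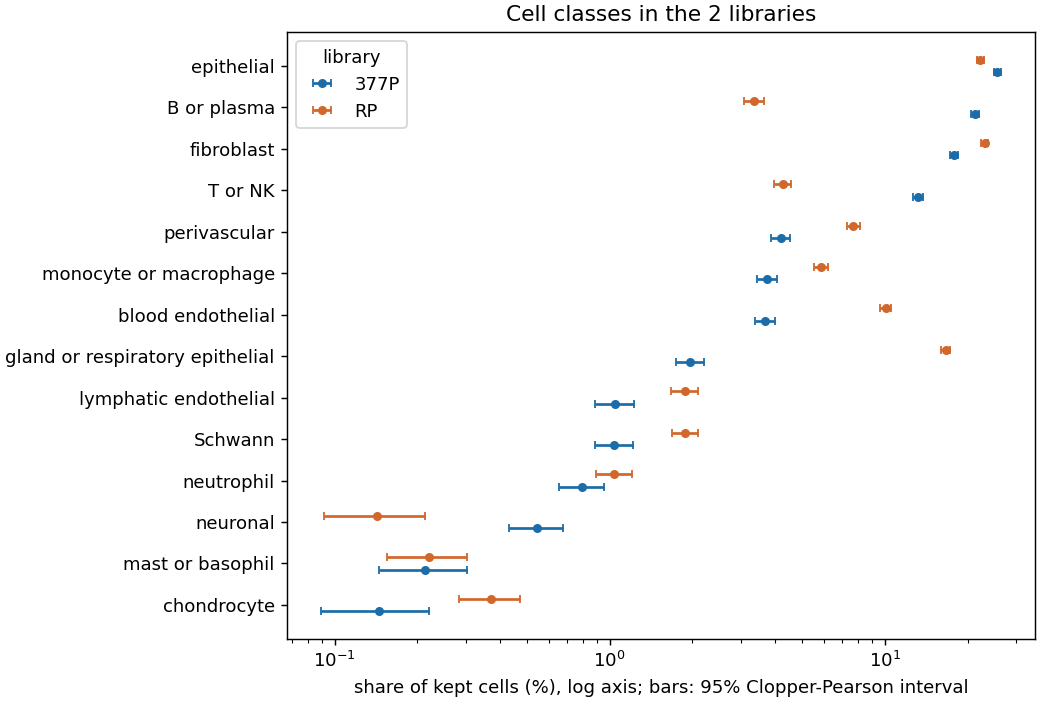
Share of the kept cells of each library in each named class, in percent on a log axis, with 377P in blue and RP in orange and bars for the 95% Clopper-Pearson interval. B or plasma cells lie at 21.3% in 377P and 3.36% in RP, and gland or respiratory epithelial cells at 1.96% and 16.6%.

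Genes of secreted proteins of nasal and gland tissue were found in every class, at levels that differed between the libraries. Obp1a, an odorant-binding protein gene of nasal tissue (ENSMUSG00000067684, chromosome X, 78085505 to 78091374), stood at 165 CPM in the fibroblasts of 377P and 0.743 CPM in those of RP. In the T or NK cells it stood at 234 and 0.410 CPM. Tff2, a secreted trefoil peptide of mucous cells, was at 533 CPM in the fibroblasts of 377P and 4305 CPM in those of RP, against 53453 and 66494 CPM in the gland class. Muc5b, a gel-forming mucin, was 7.56-fold higher in RP in fibroblasts (7.40 to 7.72) and 1.33-fold higher in the gland class (1.33 to 1.34). Under the fixed rule Obp1a, Obp1b, Obp2a and Obp2b were the leading genes of 377P in most classes, and reads of these close paralogs could be split between them by the counting. Obp2a and Obp2b were also among the leading genes of the epithelial cluster 23. In the epithelial class of 377P they stood at 285 and 201 CPM, against 126 and 83 CPM in its fibroblasts.

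**Figure D2:**
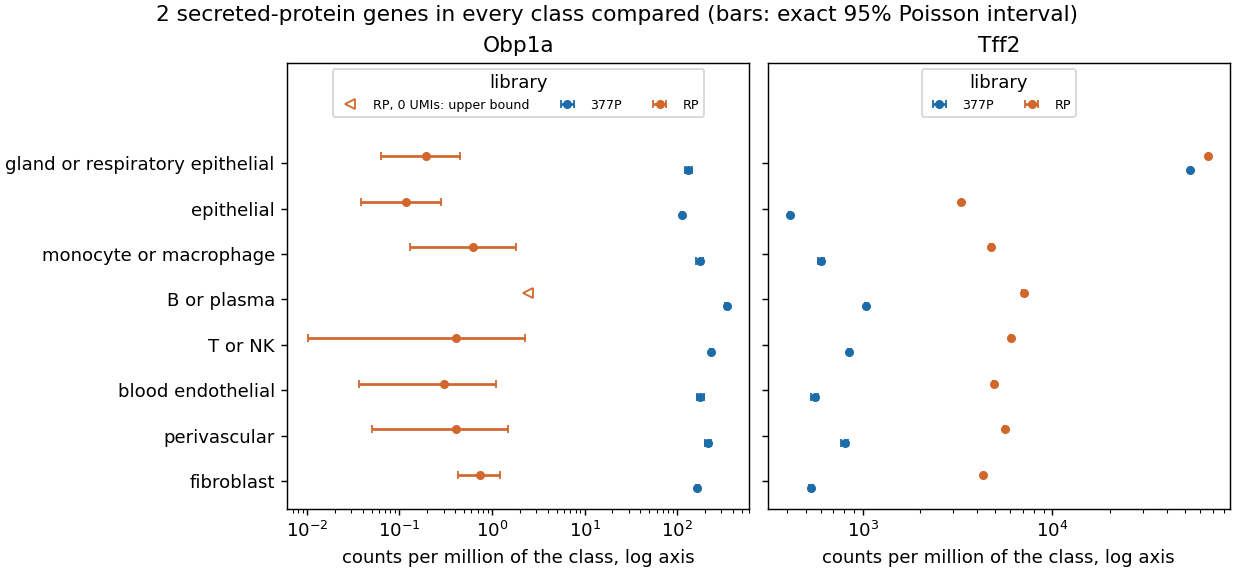
Level of Obp1a and Tff2 in each class compared, in CPM on a log axis, with 377P in blue and RP in orange, bars for the exact 95% Poisson interval and open triangles for the upper bound where 0 UMIs were counted. In fibroblasts Obp1a lies at 165 in 377P and 0.743 in RP, and Tff2 at 533 and 4305.

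In the epithelial class, genes of epithelial differentiation and barrier and of the wound and antimicrobial response stood higher in RP, and MHC class II genes stood higher in 377P. Of the 20 measured genes of epithelial differentiation and barrier, 19 were higher in RP, with a median log2 ratio of 0.83 (percentile 100). Among them, the cornified envelope genes Sprr3 and Lor were 16.1-fold and 8.72-fold higher. Of 19 measured wound and antimicrobial genes, 17 were higher in RP, at a median of 0.60 (percentile 100), with the beta-defensin gene Defb4 40.4-fold and the growth factor gene Ereg 4.81-fold higher. At Leiden resolution 2.0 Lor and Defb4 were among the leading genes of a cluster with 1 cell of 377P and 99 of RP. Cells of that kind were nearly absent from 377P, which bears on both folds. Between the basal clusters 7 and 16 alone, the median of the wound and antimicrobial list was 0.065 and no longer stood apart. MHC class II presentation had a median of -1.28 (percentile 0) over 10 genes, of which 9 were higher in 377P. In the same cells the B cell gene Cd79a was 5.54-fold higher in 377P (4.59 to 6.73), and the antibody chain gene Igkc 1.12-fold higher in RP (1.08 to 1.16).

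The epithelial genes named for RP were Amelx, Muc5ac, Cxcl5 and Ppbp. Amelx, which codes for the enamel matrix protein amelogenin (ENSMUSG00000031354, chromosome X, 169176114 to 169187200), had 16485 UMIs in RP and 3 in 377P, a fold of 7516 (2571 to 36449). It is a leading gene of cluster 23, with 378 cells of 377P and 800 of RP. At Leiden resolution 2.0 one cluster, led by Scgb1c1 and Bpifb3, held 392 cells of 377P and 1 of RP, and another, with the enamel protein gene Ambn and the keratin gene Krt15 among its leading genes, held 13 and 707, so the folds of Amelx, Scgb1c1 and Bpifb3 compare different cells. Muc5ac, a surface mucin, was 40.6-fold higher in RP (33.5 to 49.7). Cxcl5 (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624) and Ppbp are neutrophil-attracting chemokine genes, and were 17.4-fold (15.95 to 19.1) and 16.5-fold (14.2 to 19.2) higher. Both were among the leading genes of a small unnamed cluster at Leiden resolution 2.0, with 13 cells of 377P and 92 of RP. In 377P, Lcn3, a lipocalin gene, was at least 677-fold higher, with 3417 UMIs against 0. The guard added after the values were seen put Scgb1c1, Bpifb3 and Chil4 beside it, secreted protein genes that were 435-fold, 50.7-fold and 8.53-fold higher in 377P.

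Different clusters held the epithelial class in each library: clusters 6 and 7 held 902 and 2368 cells of 377P and 7 and 0 of RP, and clusters 16, 24 and 30 held 2092, 508 and 329 cells of RP and 13, 60 and 3 of 377P. Between the basal clusters 7 and 16 alone, which were 2368 cells of 377P and 2092 of RP, the log2 ratio of Cxcl5 was 0.64 against 4.12, and that of Ppbp 1.83 against 4.04. Inflammatory cytokines and chemokines had a median of 0.53 in the class (percentile 100), which was -0.0063 without members that free RNA could supply. The interferon response had 0.40 (percentile 99.1), with 19 of 21 genes higher in RP, and stood apart under 9 of 14 alternative settings. The list of insulin, lipid and diabetes-related genes had 0.19 (percentile 99.3). Without members that free RNA could supply it turned to -0.21 and stood apart on the other side (percentile 2.3). Cell cycle genes had a median of -0.15 (percentile 1.60). Between clusters 7 and 16 it was 0.053, where the list stood apart on the other side (percentile 97.7).

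In fibroblasts, genes of collagen and matrix synthesis and of matrix proteases stood slightly lower in RP as groups. Of 24 matrix synthesis genes, 23 were higher in 377P, at a median of -0.21 (percentile 0), with the matrix glycoprotein gene Tnc 2.27-fold and the proteoglycan gene Dcn 1.23-fold higher there. The protease list had a median of -0.18 (percentile 0), with the stromelysin genes Mmp10 and Mmp3 3.50-fold and 1.93-fold higher in 377P. Both lists stood apart on this side under every setting tried. Osteoclast regulation had a median of -0.27 (percentile 0.03), with the cytokine genes Lif and Il11 2.04-fold and 1.79-fold higher in 377P and Tnf and Il1b 2.22-fold and 2.04-fold higher in RP. That list had -0.16 in cluster 21 and did not stand apart there.

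Cxcl9, an interferon-induced chemokine gene (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), was 3.05-fold higher in the fibroblasts of RP (2.72 to 3.43), at 57.7 against 18.9 CPM. Jarid2, a subunit of a histone methylation complex, was 1.86-fold higher (1.77 to 1.95), the scaffold gene Dlg2 1.80-fold (1.66 to 1.95) and the transcription factor gene Dach1 1.77-fold (1.62 to 1.94). With the added guard, the genes named for 377P were the acute phase gene Saa3 at 7.81-fold (6.61 to 9.29), Igfbp2 at 3.24-fold, the collagen-binding proteoglycan gene Fmod at 3.001-fold and Myoc at 2.39-fold. Cluster 1 held 1988 cells of 377P and 11 of RP, and cluster 2 held 21 and 2870. Between these clusters alone the log2 ratio of Cxcl9 was 0.52 against 1.61. In cluster 21, which had 375 cells of 377P and 586 of RP, it was 3.14, and that of Dach1 turned to -0.17. The ratio of Dlg2 was 0.049 between clusters 1 and 2 and 1.75 in cluster 21, against 0.85.

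Other medians in fibroblasts that stood apart were -0.26 for ferroptosis and lipid peroxidation (percentile 0.04), -0.14 for myofibroblast genes and the TGF-beta response (0.24), -0.13 for Wnt and BMP targets (0.81) and -0.10 for oxidative stress (1.46). They stood apart under 14, 12, 9 and 12 of 16 alternative settings. The ferroptosis median was -0.12 between clusters 1 and 2 and -0.052 in cluster 21, and did not stand apart in either, and the oxidative stress median was 0.0498 in cluster 21. The heme oxygenase gene Hmox1 and the cystine transporter gene Slc7a11, which 2 of these lists share, had log2 ratios of -0.59 and -0.49. Periodontal ligament genes (median -0.09, percentile 11.8), osteogenic genes (0.04, percentile 94.6) and senescence genes (-0.08, percentile 16.7) did not stand apart.

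In T or NK cells, genes of interleukin-17-producing and gamma-delta T cells stood higher in RP. Of the 14 genes of that list, 13 were higher, with a median of 1.70 (percentile 100). Il17a itself (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496) stood at 355 CPM in RP and 93.0 in 377P, a fold of 3.81 (3.47 to 4.20). The gamma-delta receptor constant gene Trdc was 3.98-fold higher, the scavenger receptor gene Cd163l1 3.67-fold (3.23 to 4.17), Areg, an epidermal growth factor family gene, 4.01-fold (3.62 to 4.45), and the matrix gene Npnt 4.45-fold (3.53 to 5.62). With the added guard, the genes named for 377P were Trib2, Gimap6, Ablim1 and Frat2, at 2.14-fold, 1.78-fold, 1.63-fold and 1.82-fold.

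The T or NK class of 377P consisted mostly of cluster 11, led by the transcription factor gene Lef1, with 1394 cells of 377P and 11 of RP. Cluster 13 held 79 and 415 cells, and cluster 8, led by Il17a, 439 and 287. At Leiden resolution 2.0, leading genes of cluster 8 fell in separate clusters. One led by Il17a, Trdc and Cd163l1 held 155 cells of 377P and 167 of RP, or 1.0676% and 0.9955% of kept cells. Another led by Tnfsf8, Ctla4 and Tnfrsf4 held 287 and 120. The mix of these cells differed between the libraries, which bears on the values within cluster 8. Within cluster 8 alone the log2 ratio of Il17a was 1.15 and the list's median 0.99, and with at least 1000 UMIs per cell, where 1346 of the 1912 class cells of 377P took no name, these were 0.28 and 0.13. The ratios of Areg and Cd163l1 were 1.34 and 1.15 in cluster 8, and those of Areg, Cd163l1 and Npnt 0.45, 0.28 and 0.82 under that limit. The regulatory T (0.44, percentile 99.9) and cytotoxic (0.51, percentile 99.8) lists stood higher in RP in the class. Within cluster 8 they turned to -0.31 (percentile 1.09) and -0.40 (percentile 4.22). With at least 1000 UMIs per cell they were at -0.73 and -0.52, both at percentile 0. The regulatory T list thus stood apart on the other side in both, and the cytotoxic list under that limit. The checkpoint list (1.08, percentile 99.95) had -0.26 with at least 1000 UMIs per cell and -0.0013 in thinned cells. Cell cycle genes had a median of -0.21 (percentile 0.18), which was 0.0028 in thinned cells.

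In perivascular cells, matrix synthesis genes stood lower in RP, with a median of -0.35 (percentile 0) and 22 of 24 genes higher in 377P, among them Dcn at 1.94-fold and Lum at 1.89-fold, which are also abundant fibroblast genes. With doublets kept the median was -0.11 and the list did not stand apart. The genes named for RP were Jarid2 at 1.89-fold (1.69 to 2.12), the cytokine signalling inhibitor gene Socs2 at 1.62-fold (1.38 to 1.91), Gmds at 1.59-fold (1.35 to 1.87) and Spry2, an inhibitor of growth factor signalling, at 1.62-fold (1.34 to 1.96). With the added guard, Pcp4 was 6.67-fold higher in 377P (5.22 to 8.61), Igfbp2 2.19-fold, the BMP antagonist gene Grem1 2.31-fold and Col15a1 2.27-fold. Cell cycle genes had a median of 0.34 (percentile 99.99) and turned to -0.14 without doublet removal. The interferon response had 0.16 (percentile 98.0) and turned to -0.14 in thinned cells.

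In B or plasma cells, genes of antibody secretion stood higher in RP and MHC class II genes higher in 377P, and a different cluster held the class in each library. Cluster 4, with B cell genes in the lead, had 3005 cells of 377P and 6 of RP, and cluster 5 had 89 and 557. At Leiden resolution 2.0 a cluster led by the B cell genes Bank1, Cd79a and Pax5 held 6 cells of 377P and 540 of RP, and one with Jchain and Mzb1 among its leading genes, which mark plasma cells, held 81 and 19. Antibody secretion and unfolded protein genes had a median of 0.49 (percentile 100), with 11 of 12 higher in RP. Jchain, which joins antibody chains, was 2.24-fold higher in RP (2.15 to 2.34). Slpi, a secreted protease inhibitor gene, was 8.89-fold higher (8.34 to 9.49), at 1514 CPM against 170, and stood at 154 CPM in the gland class of RP. It was also among the leading genes of the cluster with 81 and 19 cells, so the mix of B and plasma cells bears on its fold. MHC class II genes had a median of -0.30 (percentile 0.22). In thinned cells the medians were 0.23 for antibody secretion and -0.11 for MHC class II, and neither stood apart. With the added guard, the secreted protein gene Ccer2 was 26.9-fold higher in 377P. The measured entry of Lcn11 (ENSMUSG00000069080) was 10.3-fold higher in 377P, at 13.2 CPM in RP. Yet Lcn11 was among the leading genes of the cluster with 6 and 540 cells, which takes at least 100 CPM there. Leading genes of gland cluster 28 and of an unnamed cluster at that resolution held Lcn11 too. Its direction in B or plasma cells is left open.

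In monocytes or macrophages, genes of inflammation and genes of resolution and alternative activation both stood higher in RP. The class was 1 cluster of 544 cells of 377P and 986 of RP. Resolution, efferocytosis and alternative activation had a median of 0.45 (percentile 100), with 21 of 24 genes higher in RP. The resistin-like gene Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461) was 11.6-fold higher in RP (9.86 to 13.8), and Timd4, an uptake receptor for apoptotic cells, 14.4-fold. Arg1, an arginine-degrading enzyme gene of the same list, was 2.03-fold higher in 377P. Inflammatory cytokines and chemokines had a median of 0.42 (percentile 100), with 15 of 19 genes higher in RP, among them Cxcl1 at 2.44-fold and Ccl4 at 2.02-fold. Dissociation and immediate early genes, which can mark handling of tissue, stood higher in RP in the same cells, at 0.13 (percentile 99.1). The resolution and cytokine lists stood apart on the same side under every setting tried, but at Leiden resolution 2.0 their medians were 0.27 and 0.23 and the log2 ratio of Retnla 2.86 against 3.54. At that resolution the mix of cells differed between the libraries: a cluster led by C1qa and Mrc1 held 41 cells of 377P and 205 of RP, one led by Spp1 held 280 and 447, dendritic cells 117 and 162, and an unnamed cluster led by Ctsk and Mmp9 held 108 and 174.

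The insulin, lipid and diabetes-related list had a median of 0.38 in macrophages (percentile 100), with the fatty acid transporter gene Cd36 at 2.99-fold and the fatty acid binding gene Fabp4 at 2.97-fold. The interferon response had 0.30 (percentile 100), with Ifit1 3.28-fold higher in RP, and 0.09 at Leiden resolution 2.0, where it did not stand apart. Matrix proteases had 0.36 (percentile 100), and -0.053 in thinned cells. Osteoclast effector genes had -0.32 (percentile 0.61), with Mmp9 and Ctsk 3.52-fold and 2.61-fold higher in 377P, and 0.15 at Leiden resolution 2.0. Ccdc152 was 9.85-fold higher in RP (6.24 to 16.4). With the added guard, Ccl22 and Fscn1, which were among the dendritic cell markers, were 6.97-fold and 4.28-fold higher in 377P. MHC class II genes did not stand apart in this class (median -0.07, percentile 70.7).

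In the blood endothelial class, the list of insulin, lipid and diabetes-related genes stood higher in RP, and cell cycle and MHC class II genes stood higher in 377P. Cd36 (ENSMUSG00000002944, chromosome 5, 17781690 to 17888801) was 11.8-fold higher in RP (8.70 to 16.3), and Gpihbp1, which anchors lipoprotein lipase to capillaries, 3.16-fold (2.58 to 3.90). That list, which holds Cd36, had a median of 0.34 (percentile 100), with 15 of 18 genes higher in RP. All 20 cell cycle genes were higher in 377P, at a median of -0.88 (percentile 0), which was -0.20 in thinned cells and did not stand apart there. MHC class II genes had -0.78 (percentile 0), with all 10 higher in 377P. In the same cells the B cell genes Cd79a and Igkc were 3.07-fold (2.05 to 4.65) and 2.49-fold (2.21 to 2.82) higher in 377P. In cluster 20, with 327 and 1050 cells, the log2 ratio of Cd36 was 1.38, and in cluster 3, with 205 and 641 cells, it was 4.49. That of Gpihbp1 was 0.64 in cluster 20 against 1.66.

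With the added guard, the genes named for 377P in blood endothelial cells were Glycam1, a ligand of L-selectin made in the venules of lymph nodes, at 11.1-fold (9.86 to 12.5), and the ubiquitin-like gene Ubd at 5.83-fold (4.35 to 7.90). The interferon response had a median of -0.25 (percentile 0.21), with -0.030 in cluster 3, -0.19 in cluster 20 and -0.18 in thinned cells, where it did not stand apart. Inflammatory cytokines and chemokines (0.17, percentile 99.3) and activation and angiogenesis genes (0.09, percentile 99.2) stood apart on the other side, and turned to -0.065 and -0.059 in thinned cells.

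In gland or respiratory epithelial cells, glycolysis and hypoxia genes stood lower in RP, with a median of -0.62 (percentile 0) and 20 of 21 genes higher in 377P. The list stood apart under 12 of 14 alternative settings. It did not with each library clustered on its own (-0.42) or with at most 10% mitochondrial UMIs (-0.60, percentile 13.55). Cell cycle genes had -0.51 (percentile 0.03), and 0.19 with equal weight per cell. Bpifb1, a secreted airway defence protein gene (chromosome 2, 154190818 to 154220369), had 17244 UMIs in RP and 6 in 377P, and was 377-fold higher (173 to 1027). The secretoglobin gene Scgb1b20 was at least 88.5-fold higher in RP, with 2490 UMIs against 0. Bpifb9b was 588-fold higher in 377P (391 to 930), and with the added guard Chil4 187-fold (89.0 to 473). The class had 284 cells of 377P and 2790 of RP, with median totals of 4297 and 1726 UMIs. It pooled several clusters, among them cluster 18 with 102 and 1358 cells and cluster 19 with 155 and 1302. At Leiden resolution 2.0 a cluster led by Dcpp2 held 33 and 1123 cells, and one led by Agr2 held 79 and 1029. Another, led by Pip and with Bpifb1 among its leading genes, held 120 and 435. The mix of gland cells differed between the libraries, which bears on the medians and folds of this class.

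Genes of cell dissociation and immediate early response stood higher in RP in 5 of the 8 classes. They can mark handling of tissue, but the cause was not tested. Medians were 0.21 in epithelial, 0.26 in T or NK, 0.13 in B or plasma, 0.13 in macrophage and 0.16 in blood endothelial cells. They did not stand apart with at least 1000 UMIs per cell in T or NK cells (0.021), without members that free RNA could supply in B or plasma cells (0.020) or in thinned macrophages (0.080). In the gland class they stood lower, at -0.15 (percentile 0.28), and at -0.72 with each library clustered on its own, where they did not stand apart. Nuclear genes of oxidative phosphorylation stood apart only in perivascular cells among the 8, at 0.03 (percentile 97.6), and under 8 of 16 alternative settings. Over the 94 pairs of a list and a compared class, 19 stood low in RP, 26 stood high and 49 did neither. Of the 45 that stood apart, 12 did so on the same side under every setting that gave them a value. Scaling to the median ratio and the limit of 100 cells could not change this by construction. In epithelial and blood endothelial cells, MHC class II presentation kept too few members without those that free RNA could supply. That setting gave it no value there.

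**Figure D3:**
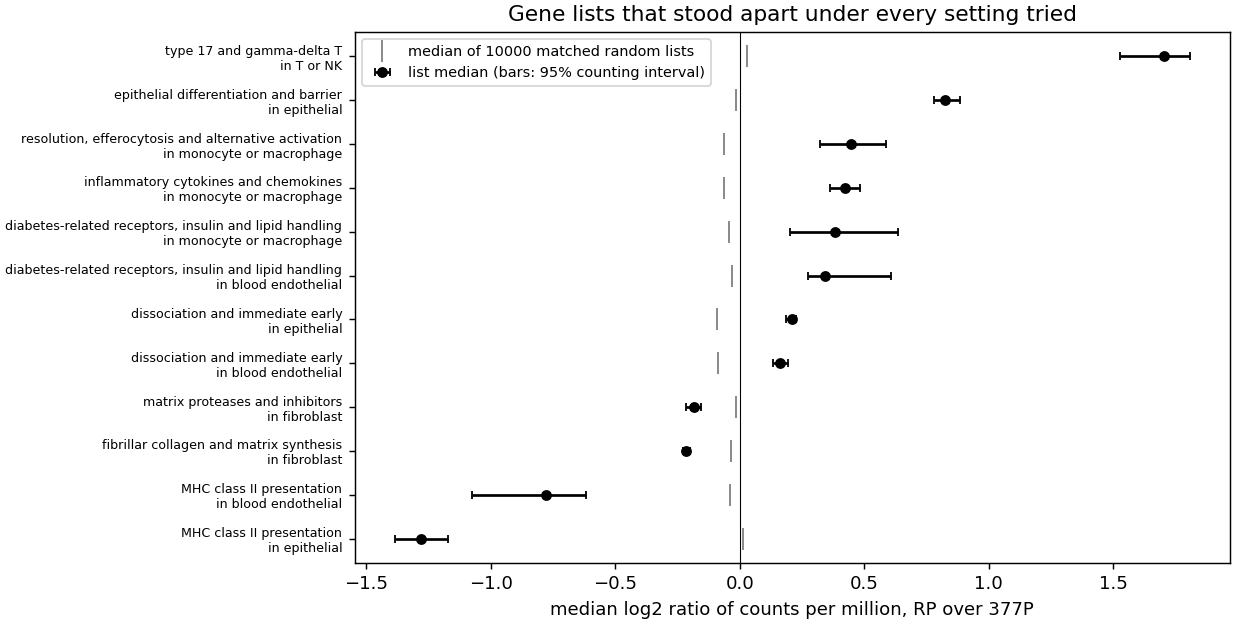
Median log2 ratio of CPM, RP over 377P, of the 12 pairs of list and class that stood apart under every setting that gave them a value. Bars show the 95% counting interval and grey marks the median of 10000 matched random lists. MHC class II presentation had no value without members that free RNA could supply. The type 17 list lies at 1.70 in T or NK cells and MHC class II presentation at -1.28 in epithelial cells.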

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

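The comparisons between classes in this part were chosen after the list medians had been seen, and none of the differences was tested. The interferon response stood higher in RP in epithelial cells (median log2 ratio 0.40) and lower in blood endothelial cells (-0.25), a difference of 0.65. The epithelial list stood apart under 9 of 14 alternative settings, and the endothelial list under 13 of 16, with -0.030 in cluster 3. Matrix proteases stood higher in RP in macrophages (0.36) and lower in fibroblasts (-0.18), a difference of 0.54, and the macrophage value was -0.053 in thinned cells. Dissociation and immediate early genes stood higher in RP in T or NK cells (0.26) and lower in the gland class (-0.15), a difference of 0.41, but the T or NK value was 0.021 with at least 1000 UMIs per cell and the gland value -0.72 with each library clustered on its own, and neither stood apart there. Cell cycle genes stood higher in RP in perivascular cells (0.34) and lower in blood endothelial cells (-0.88), a difference of 1.21, and the perivascular value turned to -0.13 in thinned cells, where neither stood apart.

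Cells of 2 clusters took no class name and entered no comparison. Cluster 0 held 686 cells of 377P, with a median of 817.5 UMIs, and 112 of RP, with Obp1a, Obp1b and Mup4 among its leading genes. Cluster 31 held 92 cells of RP and 0 of 377P, and was led by Dok6, Plppr1, Kcnip4 and Ptn.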

How the results depend on the processing

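The settings with at least 1000 UMIs per cell and with single clusters or pairs of clusters were chosen after the data had been seen. No paired analysis was possible because each title has 1 library. Over whole classes, all 48 named entries kept their direction under every setting. Of these, 22 were entries of the 4 odorant-binding protein genes that the added guard took out, whose large folds left little room to turn. In single clusters or pairs of them Dach1 alone turned, to -0.17 in cluster 21. Of the class shares, 99 values stayed within their interval, 23 moved and 2 reversed. For lists, 1150 values stayed within their interval, 230 moved and 27 reversed. Those that stayed include the values under the limit of 100 cells, which repeats the main values in the compared classes. Unless a reason stands beside a value, the cause was not tested.

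For log2 ratios of shares taken within immune or within non-immune cells, where the denominator differs by construction, values were -1.25 for B or plasma, -0.22 for T or NK, 2.06 for monocyte or macrophage, 1.80 for neutrophil and 1.46 for mast cells or basophils. They were 0.37 for Schwann, 0.97 for blood endothelial, -0.69 for epithelial, -0.11 for fibroblast, 2.60 for gland, 0.35 for lymphatic endothelial and 0.39 for perivascular cells. With at least 500 genes the epithelial value was -0.073, the fibroblast value 0.48 and the gland value 2.56. With at most 10% mitochondrial UMIs the epithelial value was -0.12, the gland value 1.94 and the neuronal value -0.42. With each library clustered on its own the epithelial value was -0.12 and the gland value 0.99. The gland value was 3.27 with doublets kept, and the macrophage value 0.81 at Leiden resolution 2.0. With at least 1000 UMIs per cell the T or NK value was 0.22, where 1346 of the 1912 cells of 377P fell in clusters without a name and 24 were left out, the fibroblast value 0.47 and the gland value 2.56.

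Thinning to 1000 UMIs left 12 lists low and 17 high in RP. In thinned cells, reversed medians were -0.065 for cytokines and -0.059 for activation in blood endothelial cells, -0.14 for interferon and -0.13 for cell cycle in perivascular cells, -0.053 for proteases in macrophages, and -0.0013 for checkpoint and 0.0028 for cell cycle genes in T or NK cells. With equal weight per cell they were -0.070 for cytokines and -0.24 for activation in blood endothelial cells, -0.021 for interferon and -0.16 for cell cycle in perivascular cells, and 0.19 for cell cycle in the gland class. Without members that free RNA could supply, epithelial cytokines had -0.0063 and the diabetes-related list -0.21. At resolution 2.0 osteoclast effectors had 0.15 in macrophages, and with doublets kept the perivascular cell cycle list had -0.14.

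In the T or NK class left by the limit of 1000 UMIs per cell, medians were -0.73 for regulatory, -0.52 for cytotoxic and -0.26 for checkpoint genes. The first 2 of these stood apart on the other side. In cluster 8 medians were -0.31 for regulatory genes, also apart on the other side, and -0.40 for cytotoxic genes. Cluster 9 had -0.13 for interferon and -0.16 for cell cycle, and cluster 10 had -0.055 for oxidative phosphorylation. Cluster 20 had -0.020 for activation, cluster 21 had 0.0498 for oxidative stress, and clusters 7 and 16 had 0.053 for cell cycle.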

Other observations

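The tests on gland RNA, on lymphoid tissue genes and on the share of MHC class II UMIs that markers predict were chosen after the result was seen, as were the classes described next, which were run under 1 setting. In neutrophils, with 115 cells of 377P and 174 of RP, genes of granules and immaturity stood lower in RP, at a median log2 ratio of -0.40 (percentile 0). The antimicrobial genes Camp and Ltf were 1.52-fold and 1.48-fold higher in 377P. Of 15 genes of aged or activated neutrophils, 9 were higher in RP and 6 in 377P, and their median of 0.24 (percentile 99.9) had a counting interval of -0.00090 to 0.31. Their dissociation and immediate early genes stood higher in RP as well, at 0.47 (percentile 100).

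In lymphatic endothelial cells, with 152 cells of 377P and 315 of RP, all 20 cell cycle genes were higher in 377P, at a median of -1.17 (percentile 0), and in Schwann cells the list had -0.57 (percentile 0.03). The diabetes-related list stood higher in RP in lymphatic endothelial cells, at 0.35 (percentile 99.96), and Cd36 had 34 UMIs in RP against 2.

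Gland secretory genes stood higher in RP in each of the 7 classes compared other than the gland class, and free RNA from gland cells may have supplied them. One source keeps its genes in 1 ratio in every class: over 7 classes of RP, the SD of the log2 share of 8 gland genes had a median of 0.107. This is what 1 source needs, and more than 1 pool of free RNA with a like composition stays open. The 8.50-fold larger share of gland cells in RP could come from the piece of tissue taken or from the animals, which was not tested. It also rests on cluster 18, led by Dcpp2 and Dcpp3, which held 102 cells of 377P and 1358 of RP. Their medians were 923 and 696.5 UMIs, where the lowest barcode total was 500. Whether these barcodes hold gland cells or mostly free RNA was not tested. With each library clustered on its own the log2 ratio of gland shares was 0.99 against 3.09.

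MHC class II genes stood lower in RP in blood endothelial cells, fibroblasts and epithelial cells, and RNA of B cells and macrophages could have supplied them. The test laid down before its result, although the direction had been seen, took out the UMIs that B cell and macrophage markers predict, after which the median log2 ratio of 7 genes in blood endothelial cells was -1.22 against -0.95 before. That met the condition set against such RNA, but 4 of the 7 genes were at the floor in one library or the other (5 of 7 in fibroblasts, at -0.295 against -1.58), so the test decides nothing; this ground for leaving the test undecided was set after its values were seen. In a later test the markers predicted 90.2% of the MHC class II UMIs in blood endothelial cells of 377P and 112.8% in RP, 96.9% and 139.5% in fibroblasts, and 100.3% and 138.0% in epithelial cells. Values above 100% show that this prediction overshoots, Igkc was 1.12-fold higher in RP in epithelial cells, and whether cells of these classes in 377P carried such transcripts of their own stays open.

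B cells were a larger share of 377P, and organised lymphoid tissue caught with that piece may be a source. Of 11 genes of lymphoid venules and stroma, 8 were measured, and their median log2 ratio was -1.08, narrowly past the limit of -1 that had been set after Glycam1 and the shares were known. Cr2, at 17.1-fold higher in 377P with 49 UMIs against 3, is also a B cell gene, and Cd79a was 6.57-fold higher in the same fibroblasts; the median was -1.07 without Glycam1, and without Cr2 as well that of the other 6 genes was -0.77, short of that limit. Of the 8 genes 6 were higher in 377P, while the venule gene Chst4 was 3.38-fold higher in RP, and this explanation stays open. A difference between the animals or treatments behind the titles cannot be told apart from the sampling of tissue with 1 library per title.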
